A study of Mus musculus with 16 samples.

How the data were processed

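Total RNA from the hippocampus of 16 female 3xTg-AD mice was measured on Affymetrix arrays, 8 from animals on a control diet and 8 from animals on a PIO diet. Each array was of a separately numbered subject, per the labels, so the animal is the replicate. The PIO diet was given at 84 ppm, per the labels. Behavioural and electrophysiological measurements were not analysed here.

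The deposited values are 1 number per probe set and array on a log2 scale, with the scale taken from the values themselves. MAS5, GCRMA and R 2.7.1 are named without a role, per the submitters' processing notes. The values run from 0.33 to 16.6, with column medians of 5.65 to 5.76 and no negative value, as a log2 summary by GCRMA would give, but which of the named methods made them is not given in the sources used here. GCRMA subtracts a background modelled from probe sequence, which sets unexpressed probe sets to a narrow band of low values and can enlarge differences of genes just above it. Detection calls and scanner files were not used here. The values were taken as already normalized between arrays, and no pseudocount was added. The plan had allowed for linear values with a pseudocount, and that alternative was not needed.

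The table held 45101 probe sets, of which 64 hybridization and labelling controls were left out. Gene symbols came from the platform annotation paired with the values. Of the others, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none here, and only those with 1 symbol were named. The Entrez identifiers of 34754 of these were found in a RefSeq gene table, and 0 symbols changed. Probe sets with a mean over all 16 arrays above the 40th percentile (3.58 log2 units) were kept, 22811 in all. The probe set with the highest mean stood for each gene, which left 12266 genes. No genome build is named for the arrays in the sources used here, so no coordinates are given.

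Group differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment over all genes. Differences are PIO minus control on the log2 scale, each with the moderated SE. Gene lists of 21 pathways and 17 cell or tissue types were fixed before the data were examined, as were the test of groups, the rule for naming genes and most of the other settings. The rule took the 12 higher and the 12 lower genes with the largest change among those past the threshold, filled by smallest p where too few passed, up to 3 members of each list with the smallest p, and a fixed set of PPAR, Alzheimer's disease, glial, synaptic and insulin genes, of which 2 are not reported here. Lists with 5 or more measured genes were tested with limma's camera at the preset inter-gene correlation of 0.01, adjusted over the 37 lists tested. Camera compares a list with all other genes, and the preset correlation takes the members to vary nearly independently between animals. Lists that share a cell type have members that vary together, so camera was repeated with the correlation estimated for each list. Fry, which tests whether a list's genes move one way on balance and does not compare the list with other genes, was run as well. An exact permutation of the array means over 12870 rearrangements was added after the data were seen. Of the measured list members 42 stood on more than 1 list.

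On data simulated from the 12266 genes, with 50 genes changed at each size, the same fit recovered 36% of genes changed by 0.25 log2 units, 90% at 0.5, 88% at 1 and 98% at 2, with 8 unchanged genes called. In the list simulation 0 of 37 lists were called with no shift and 1 when the microglial list was shifted by -0.2. Genes were drawn independently in both simulations, which is close to what the preset correlation assumes. The list simulation therefore does not show how often lists are called when their members vary together. In the gene simulation the changed genes of all sizes stood in the same data. That makes the adjusted threshold easier to pass than where few genes change. The recovery rates therefore do not give the power behind a real count of 0.

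A code at the end of each array description was read as the array batch, and its meaning is not given in the sources used here. It forms 3 batches, with 5 control and 6 PIO arrays, 2 control and 1 PIO, and 1 of each. The array number at the start of the description was 1 to 6 in 4 control and 2 PIO arrays and 10 to 24 in 4 control and 6 PIO arrays, and its meaning is likewise not given. The other settings fixed then were no filter and a filter at the 60th percentile (7.39 log2 units), every probe set on its own, probe sets with shared sequence left out, quantile normalization, a common median, batch as a block, the largest batch alone, a trended and robust prior, array weights, the choroid or the myelin list mean as a covariate, each animal left out in turn, and a plain two-sample test. Settings chosen after seeing the data were the striatal list mean as a covariate, the choroid, striatal and thalamic means together as covariates, the fit without PIO animals 14, 15 and 16, the 2 ranges of array number as a block, arrays 10 to 24 alone, and the exact permutation of array means. Correlations between list means used deviations from each group's mean and 100000 permutations. The group labels were also compared with 100 splits of the arrays into 8 and 8.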

Results

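Hippocampal RNA was profiled on 16 Affymetrix mouse arrays, 1 per animal. All animals were 14-month-old female 3xTg-AD mice, a model of Alzheimer's disease that carries mutant human APP and tau transgenes. From 10 months of age, 8 animals received a control diet and 8 received a diet with pioglitazone (PIO) at about 18 mg per kg body weight per day, for about 14 weeks. PIO is a thiazolidinedione, a class of drugs that activate the nuclear receptor PPAR gamma. The deposited values were log2 expression per probe set. They lay between 0.33 and 16.6, with array medians of 5.65 to 5.76, and pairs of arrays correlated with r between 0.979 and 0.996. The number of arrays limits the precision of every difference given here.

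The comparison asked which hippocampal genes and gene groups differed between PIO-fed and control-fed animals. By limma's camera with its preset inter-gene correlation, genes of oligodendrocytes and myelin, microglia, astrocytes and disease-associated microglia fell with PIO, as did genes of cholesterol efflux, fatty acid synthesis and oxidative phosphorylation, and genes of the choroid plexus and ependyma rose. None of these 8 lists kept its call with an estimated correlation, where the smallest adjusted p of any list was 0.527. Over other splits of the arrays into 8 and 8, camera's preset test called a median of 9 lists. Of 100 splits, the real one included, 63 called as many lists as the real one or more, so chance cannot be excluded for this count. The shifts were small apart from the choroid plexus genes, with list means between -0.22 and -0.016 log2 units for the lists that fell and 0.92 for the one that rose. A number in each array's label ran from 1 to 6 in control animals 1 to 4 and PIO animals 9 and 10, and from 10 to 24 in the others. In arrays 10 to 24 alone, a choice made after the values were seen, only the myelin and astrocyte lists of the 8 kept their calls. Those arrays include PIO animals 14 and 15, in which the myelin list was lowest and striatal markers were highest.

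No single gene passed an adjusted p of 0.05 in limma's test of 12266 genes, and the smallest adjusted p was 0.457. At an unadjusted p under 0.05 there were 859 genes, 473 higher and 386 lower with PIO, where 613 would be expected by chance. Of 100 splits of the arrays into 8 and 8, the real one included, 20 gave as many genes or more. The highest of the other splits gave 2329, so the excess over 613 is not evidence of a diet effect. A plain two-sample test with equal variances gave 0 genes after adjustment and 835 before it. The median absolute log2 difference of a gene was 0.050, below the median SE of 0.064. Only 25 genes differed by 1 log2 unit or more, none of them past the adjusted threshold.

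The genes with the smallest p among those higher with PIO did not pass the test, and their values are given as descriptions. Gopc, a Golgi-associated protein that routes membrane proteins, was at 10.30 ± 0.051 log2 units in controls and 10.46 ± 0.035 with PIO (SD, n = 8 each), and all 8 PIO arrays lay above the highest control. Sstr1, a somatostatin receptor, had a log2 difference of 0.44 (SE 0.088), a 1.35-fold higher level. Rps6ka6, a ribosomal S6 kinase, had a difference of 0.20 (SE 0.044) with the PIO arrays above the highest control in 8 of 8 animals. The galactosyltransferase genes C1galt1 and B3galt1 had differences of 0.37 (SE 0.078) and 0.40 (SE 0.086). Rxrg, which encodes retinoid X receptor gamma, a dimer partner of the PPARs, was at 5.23 ± 0.18 in controls and 5.84 ± 0.41 with PIO (SD, n = 8 each), again with every PIO array above the highest control. Of the others, Shb, Zfp248, Spin2c, Tmem35a and Trub1 differed by between 0.16 and 0.25, and AW551984 by 0.99 (SE 0.25). Adjusted p from limma was between 0.457 and 0.532 for all 12.

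Among the lower genes, the smallest p belonged to Cx3cr1, the fractalkine receptor that marks microglia. Its level was 10.11 ± 0.23 in controls and 9.66 ± 0.16 with PIO (SD, n = 8 each), and 7 of 8 PIO arrays lay below the lowest control. Its adjusted p over all genes was 0.457, and its 2 probe sets moved the same way. Hsd11b1, whose enzyme regenerates active glucocorticoid, had a log2 difference of -0.44 (SE 0.11). The myosin heavy chain gene Myh7b had a difference of -0.41 (SE 0.088). Mylip, whose product marks lipoprotein receptors for degradation, differed by -0.26 (SE 0.064). Il1rap, the accessory chain of the interleukin 1 receptor, and Sptb, a beta spectrin, differed by -0.18 (SE 0.043) and -0.19 (SE 0.045). Arhgef4, Aff3, Stac2, Mindy1, Prrg1 and Rgs11 had differences between -0.28 and -0.18 log2 units. None of these 12 genes passed the test.

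**Figure D1:**
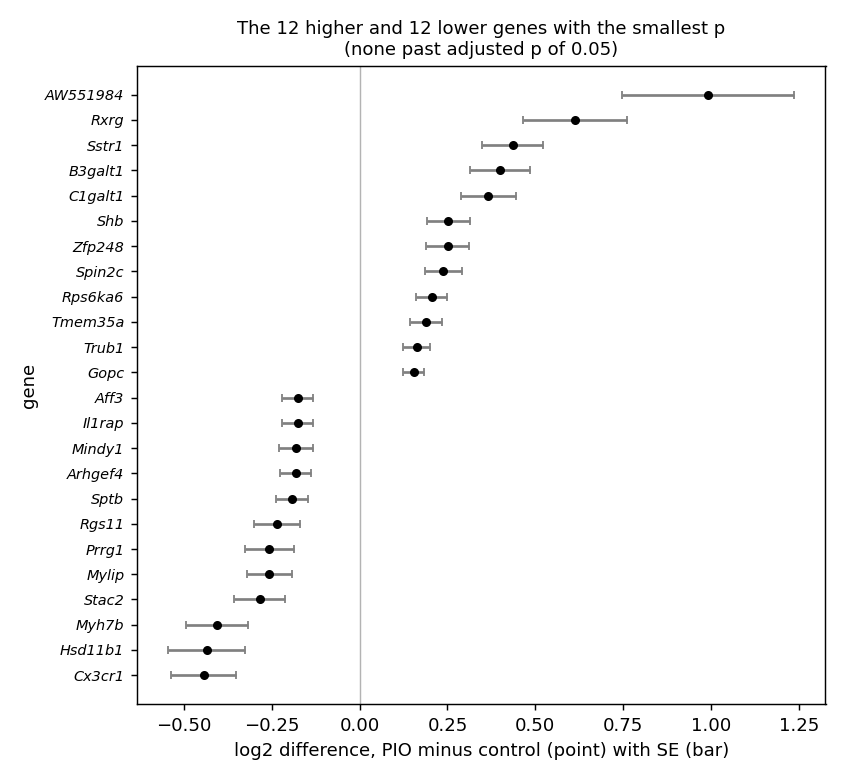
Log2 difference between PIO-fed and control-fed animals (PIO minus control, horizontal axis) for the 12 higher and 12 lower genes with the smallest p, each point with its SE as a bar. The points run from -0.44 for Cx3cr1 to 0.99 for AW551984, and none passed an adjusted p of 0.05.

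Genes of oligodendrocytes and myelin fell together. Of 25 measured members, 24 were lower with PIO, with a median log2 difference of -0.19 and a mean of -0.18 (camera adjusted p = 2.42e-10; adjusted p = 0.527 with an estimated correlation). Per animal, the mean of the list relative to all 16 arrays was 0.092 ± 0.17 in controls and -0.092 ± 0.20 with PIO (SD, n = 8 each), a difference smaller than the SD between animals fed PIO, with an exact permutation p of 0.0659. At an unadjusted p under 0.05 there were 8 members, all lower, and 0 passed when adjusted over the list alone, where the smallest adjusted p was 0.0725. Aspa, which breaks down N-acetylaspartate in oligodendrocytes, had a difference of -0.35 (SE 0.11). Fa2h, which makes hydroxylated myelin lipids, and the receptor gene Gpr37 had differences of -0.29 (SE 0.092) and -0.29 (SE 0.11). Mbp, the abundant myelin basic protein gene, differed by -0.036 (SE 0.040), and its 8 probe sets moved the same way. The list was lowest in PIO animals 15 and 14, at -0.50 and -0.25, the 2 animals with the highest striatal marker means (0.74 and 0.63). Its mean was -0.091 with the striatal list mean as a covariate and -0.11 without PIO animals 14 to 16, both choices made after the values were seen, and it stayed past the threshold in each (adjusted p = 5.32e-04 and 5.77e-04). In the largest array batch alone, with 5 control and 6 PIO arrays, the list mean was -0.066 (camera adjusted p = 0.00197). With batch as a block it was -0.19. The array means in the largest batch differed by -0.0663 (SE 0.0815), less than the SE, and camera's p does not measure this spread between animals. In arrays 10 to 24 the list mean was -0.26 (camera adjusted p = 3.13e-14). PIO animals 14 and 15 are 2 of the 6 PIO animals in those arrays. Precursor markers were not called, with 8 of 13 lower, a mean of -0.021 and an adjusted p of 0.355. Their mean ranged from -0.042 (without PIO animal 12) to -0.0028 (without PIO animal 16) with 1 animal left out. Among them, Olig1 differed by -0.15 (SE 0.079), Matn4 by -0.13 (SE 0.082) and Sox10 by -0.12 (SE 0.097).

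Microglial genes also fell, with 23 of 24 measured members lower, a median of -0.20 and a mean of -0.22 (camera adjusted p = 1.16e-09; adjusted p = 0.527 with an estimated correlation). The array means were 0.11 ± 0.25 in controls and -0.11 ± 0.19 with PIO (SD, n = 8 each), with an exact permutation p of 0.0608. Cx3cr1 passed when adjusted over the list alone (adjusted p = 0.00499), the only member to do so. Csf1r, the receptor that microglia need to survive, differed by -0.21 (SE 0.072), and Cd53, a leukocyte tetraspanin, by -0.34 (SE 0.13). Aif1, which encodes the microglial protein IBA1, differed by -0.12 (SE 0.075). The list mean was -0.14 in the largest array batch (camera adjusted p = 2.30e-04) and -0.24 with batch as a block. The array means in the largest batch differed by -0.138 (SE 0.138), about the size of the SE, a spread between animals that camera's p does not measure. In arrays 10 to 24 the list mean was -0.077 and the call was lost (adjusted p = 0.0592).

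The disease-associated microglia genes, a set described in amyloid-bearing brain, had 17 of 22 members lower, with a median of -0.12 and a mean of -0.19 (camera adjusted p = 0.00118; adjusted p = 0.678 with an estimated correlation). Ctsz, a lysosomal cathepsin, differed by -0.25 (SE 0.11) and Apoe, the main lipid carrier of the brain, by -0.16 (SE 0.070). Timp2, an inhibitor of matrix metalloproteinases, went the other way at 0.20 (SE 0.054) and passed when adjusted over the list alone (adjusted p = 0.0499). The call was lost with the myelin covariate (-0.092, adjusted p = 0.287), with the striatal covariate (-0.12, adjusted p = 0.0567) and without PIO animals 14 to 16 (-0.11, adjusted p = 0.0743). With the filter on low values at the 60th percentile the list mean was -0.088, and in arrays 10 to 24 it was -0.050 with the call lost (adjusted p = 0.163). Complement and inflammation genes were not called, with 14 of 20 lower, a median of -0.10 and an adjusted p of 0.0706. That list passed as lower with batch as a block (adjusted p = 0.0276), without probe sets of shared sequence (adjusted p = 0.0293), with the choroid covariate (-0.14, adjusted p = 0.00177) and without control animal 4, 5, 6 or 7 or PIO animal 11 or 12 in turn, with adjusted p between 0.00881 and 0.0430, while in arrays 10 to 24 its mean was 0.081. With 1 animal left out its mean ranged from -0.12 (without control animal 5) to -0.033 (without control animal 3, adjusted p = 0.215). In that list Ccl6 differed by -0.53 (SE 0.27), Osmr by -0.28 (SE 0.17) and Cxcl10 by -0.23 (SE 0.14), and without control animal 8 the difference for Cxcl10 was -0.091 (SE 0.057). Genes of MHC class I and interferon had a median of -0.037 and a mean of 0.022, opposite in sign, and a test direction of lower (adjusted p = 0.215). They passed as lower in the largest array batch (-0.15, adjusted p = 0.00274), with the choroid covariate (-0.11, adjusted p = 0.00193), with the myelin covariate (-0.093, adjusted p = 0.0439), with the choroid, striatal and thalamic covariates (-0.16, adjusted p = 0.00137) and without PIO animal 11 (-0.067, adjusted p = 0.0204), and their mean was 0.11 (adjusted p = 0.680) without PIO animal 10. H2-K1 differed by -0.23 (SE 0.12), Irf9 by -0.22 (SE 0.092) and Psmb8 by -0.12 (SE 0.064).

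Astrocyte genes fell by a smaller amount, with 17 of 22 members lower, a median of -0.067 and a mean of -0.062 (camera adjusted p = 0.00129; adjusted p = 0.584 with an estimated correlation). Slc1a2, the main astrocytic glutamate transporter, differed by -0.12 (SE 0.050), the lipid enzyme gene Acsbg1 by -0.17 (SE 0.073) and the folate enzyme gene Aldh1l1 by -0.16 (SE 0.072). Gfap, which rises in reactive astrocytes, differed by -0.26 (SE 0.18). None of the list passed when adjusted over the list alone. The call was lost with the myelin covariate (-0.020, adjusted p = 0.226), with the striatal covariate (-0.024, adjusted p = 0.125), with the choroid, striatal and thalamic covariates (-0.040, adjusted p = 0.0532) and without PIO animals 14 to 16 (-0.020, adjusted p = 0.335). The array means were -0.19 and -0.14 in PIO animals 15 and 14, where striatal markers were highest. Without PIO animal 15 alone the list mean was -0.040, still past the threshold at an adjusted p of 0.0162, and in arrays 10 to 24 it was -0.031 (adjusted p = 0.0178).

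**Figure D2:**
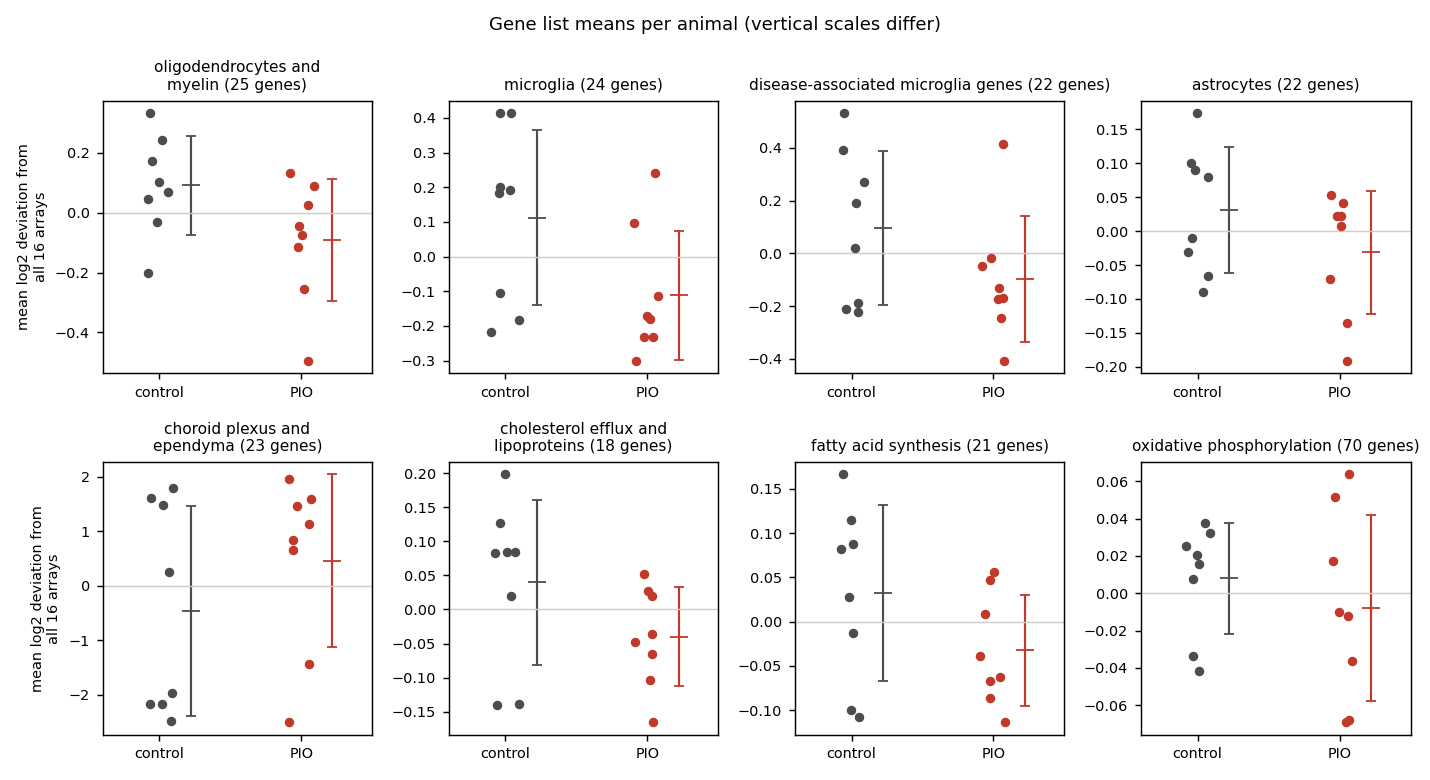
Mean log2 deviation of each gene list from the mean of all 16 arrays (vertical axis, scales differ between panels), 1 point per animal with the group mean and SD beside the points, for the 8 lists called by camera. The groups overlap in every panel; the microglial means are 0.11 in controls and -0.11 with PIO, and the choroid plexus points split into a high and a low set in both groups.

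Genes of cholesterol efflux and lipoproteins fell, with 13 of 18 members lower, a median of -0.051 and a mean of -0.080 (camera adjusted p = 0.00384; adjusted p = 0.527 with an estimated correlation). Mylip passed when adjusted over the list alone (adjusted p = 0.0173). Abcg1 and Abca1, which move cholesterol out of cells, differed by -0.18 (SE 0.062) and -0.42 (SE 0.18). Abca1 was at 11.09 ± 0.49 in controls and 10.67 ± 0.27 with PIO (SD, n = 8 each), and its 3 probe sets moved the same way. Control animals 1 to 4 lay between 11.45 and 11.61, and control animals 5 to 8, between 10.50 and 10.75, lay within the PIO range of 10.35 to 11.04. In arrays 10 to 24 the difference for Abca1 was -0.032 (SE 0.13), and the list mean was 0.026 with the call lost (adjusted p = 0.503). Fatty acid synthesis genes fell as well, with 14 of 21 members lower, a median of -0.074 and a mean of -0.064 (camera adjusted p = 0.00832; adjusted p = 0.678 with an estimated correlation). The stearoyl-CoA desaturase genes Scd1 and Scd2 differed by -0.38 (SE 0.16) and -0.12 (SE 0.048), and Gpam, the first enzyme of glycerolipid synthesis, by -0.16 (SE 0.059). For Scd1, control animals 1 to 4 lay between 12.53 and 12.77, control animals 5 to 8 between 11.74 and 11.85 and PIO animals between 11.67 and 12.05, and in arrays 10 to 24 the difference was 0.026 (SE 0.073). The array means of the fatty acid list were 0.082 to 0.17 in control animals 1 to 4 and -0.11 to 0.028 in control animals 5 to 8. Its call was lost in arrays 10 to 24 (0.0023, adjusted p = 0.498) and with the 2 ranges of array number as a block (-0.036, adjusted p = 0.0716). It was lost as well with the myelin covariate (-0.035, adjusted p = 0.266), with the striatal covariate (-0.037, adjusted p = 0.195), with the choroid, striatal and thalamic covariates (-0.054, adjusted p = 0.152) and without PIO animals 14 to 16 (-0.057, adjusted p = 0.141). The fatty acid call was also lost without control animal 2, at a mean of -0.045 and an adjusted p of 0.102. Cholesterol synthesis genes were not called, with 12 of 20 higher, a mean of 4.10e-04 and an adjusted p of 0.998. Cyp51, Hmgcs1 and Mvk, all enzymes of that pathway, differed by 0.078, 0.096 and -0.17, each by less than 2 of its SE.

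Oxidative phosphorylation genes fell by little, with 51 of 70 lower, a median of -0.023 and a mean of -0.016 (camera adjusted p = 0.00978; adjusted p = 0.803 with an estimated correlation). Ndufv1, a subunit of complex I, differed by -0.094 (SE 0.040), Atp5c1, of the ATP synthase, by -0.083 (SE 0.044) and Ndufa13 by -0.065 (SE 0.035). The call was lost without control animal 8 (mean -0.012, adjusted p = 0.0825), without PIO animal 10 (-0.0074, adjusted p = 0.0705) and without PIO animal 11 (-0.0072, adjusted p = 0.0739). It was also lost after quantile normalization (-0.011, adjusted p = 0.0961), in the largest array batch (-0.014, adjusted p = 0.252), with array weights (-0.010, adjusted p = 0.0509) and in arrays 10 to 24 (-0.0043, adjusted p = 0.0602). With the myelin covariate it was lost at -0.0096 (adjusted p = 0.378). Without PIO animals 13 and 16 in turn the mean was -0.026 and -0.024, and it was -0.032 without PIO animals 14 to 16 and with the choroid, striatal and thalamic covariates.

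The PPAR target genes, the canonical lipid genes of these receptors, were not called as a group. Of 24 measured members, 12 were higher and 12 lower. The median was -2.88e-04, the mean 0.032 and the test direction lower, so the mean differed in sign from the other measures (camera adjusted p = 0.793). The mean ranged from 0.0030 (without control animal 5) to 0.057 (without PIO animal 9) with 1 animal left out. With the choroid list mean as a covariate the list passed as lower, at a mean of -0.023 and an adjusted p of 0.0211. Cd36, a fatty acid transporter, was at 4.38 ± 0.23 in controls and 5.16 ± 0.78 with PIO (SD, n = 8 each), not far above the filter of 3.58, with an adjusted p of 0.654. Angptl4 and Pdk4, induced by PPARs in many tissues, differed by 0.14 (SE 0.074) and 0.086 (SE 0.14), and Lpl, the lipoprotein lipase gene, by -0.22 (SE 0.12). Receptors and coregulators of the PPAR and RXR family had 10 of 14 members higher, a mean of 0.058 and an adjusted p of 0.330. By exact permutation of the array means, which does not set the list against other genes, the p for this list was 0.0210 and 0.664 after adjustment. Rxrg passed when adjusted over the list alone (adjusted p = 0.0107). It was highest in PIO animals 14 and 15, at 6.56 and 6.39 against 5.46 to 5.81 in the other PIO animals, and striatal markers were also highest in these 2 animals. Its difference was 0.42 (SE 0.093) without PIO animals 14, 15 and 16 and 0.43 (SE 0.098) with the striatal list mean as a covariate. Ppara, Ppard, Rxra and Ppargc1a had differences of 0.071, 0.027, 0.065 and 0.034, none past 2 SE, and without PIO animal 11 that of Ppara was 0.0093 (SE 0.030). Pparg, the receptor of the drug, had 1 probe set with a mean of 3.43, below the filter, and without the filter its difference was 0.089 (SE 0.064).

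**Figure D3:**
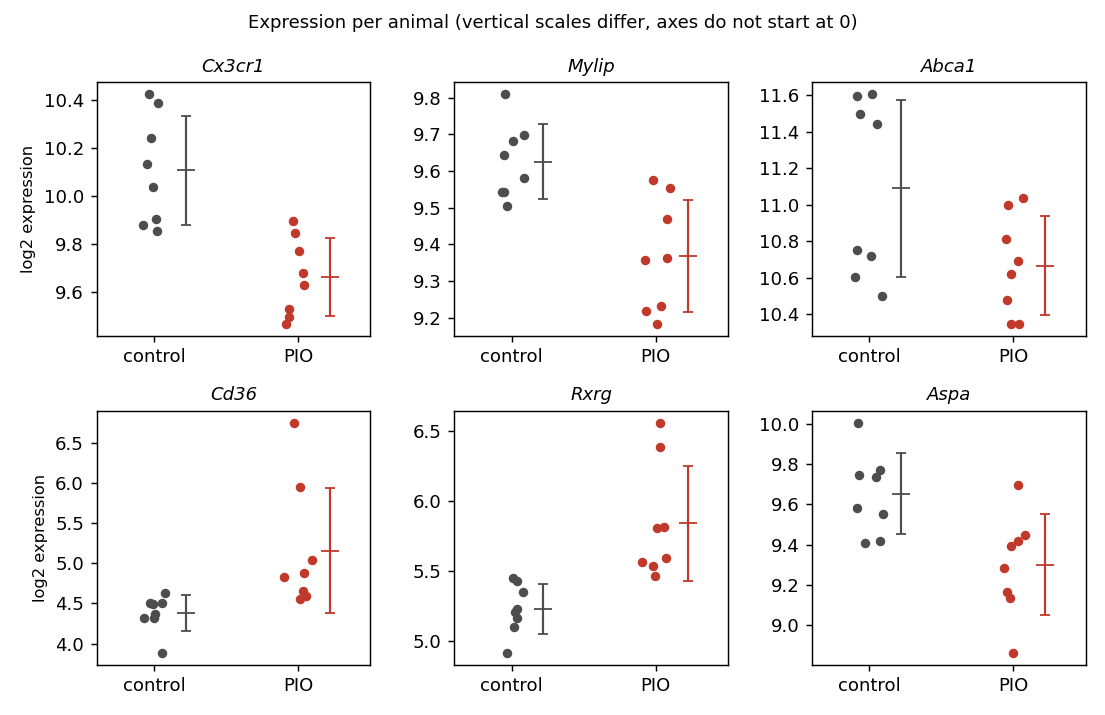
Log2 expression per animal (vertical axis, scales differ between panels and do not start at 0) for Cx3cr1, Mylip, Abca1, Cd36, Rxrg and Aspa, 1 point per animal with the group mean and SD beside the points. Cx3cr1 was at 10.11 in controls and 9.66 with PIO, and all 8 PIO points for Rxrg lie above the highest control.

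Genes of Alzheimer's disease pathways showed small differences with no list called. In the amyloid precursor list 12 of 21 members were lower, with a mean of -0.0059 and an adjusted p of 0.665. App differed by -0.0085 (SE 0.032), Bace1, the beta-secretase gene, by 0.019 (SE 0.068) and Aph1a, of the gamma-secretase complex, by -0.15 (SE 0.061). The sorting receptor gene Sorl1 and the adaptor gene Apba2 differed by -0.10 (SE 0.053) and -0.083 (SE 0.049). The tau list had 10 members higher and 10 lower, with a median of 0.0028, a mean of -0.0087 and an adjusted p of 0.746 in the direction of lower. Mapt differed by 0.045 (SE 0.046). The tau kinase gene Gsk3b differed by -0.31 (SE 0.11), but only 3 of its 6 probe sets moved that way.

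Synaptic, calcium and activity genes were likewise not called in the planned fit, with group as the only term and none of the other settings applied. Calcium channels and calcium handling had 22 of 36 lower, a mean of -0.022 and an adjusted p of 0.0618. That list passed as lower with no filter or the filter at the 60th percentile, with a trended prior, with array weights, in arrays 10 to 24 and without control animal 2 or 3 or PIO animal 10 or 11 in turn, with adjusted p between 0.0115 and 0.0476, while in the largest array batch its mean was -0.0020 (adjusted p = 0.596). With 1 animal left out its mean ranged from -0.030 (without control animal 2) to -0.013 (without control animal 4, adjusted p = 0.101). The sodium-calcium exchanger gene Slc8a1 differed by -0.38 (SE 0.13), the ryanodine receptor gene Ryr2 by -0.14 (SE 0.049) and Fkbp1b, which steadies ryanodine receptors, by -0.14 (SE 0.060). Only 1 of the 2 probe sets of Ryr2 moved that way. Glutamate receptor and postsynaptic genes had 19 of 33 lower and an adjusted p of 0.355, with Grm3 at -0.23 (SE 0.080), Grin2a at -0.40 (SE 0.19) and Grin3a at 0.21 (SE 0.087). Presynaptic genes had a median of 0.0024 and a mean of -0.0034, with an adjusted p of 0.643 in the direction of lower, and passed as lower with the myelin covariate (-0.044, adjusted p = 0.0426). With 1 animal left out their mean ranged from -0.024 (without control animal 2) to 0.0077 (without PIO animal 10). Syt2, Vamp1 and Cplx1, all of vesicle release, differed by -0.43 (SE 0.14), -0.15 (SE 0.060) and -0.089 (SE 0.047). Immediate early genes had 17 of 25 lower, a mean of -0.055 and an adjusted p of 0.190. They passed as lower without PIO animal 15 (-0.091, adjusted p = 0.0295), with the myelin covariate (-0.11, adjusted p = 0.0262) and with the striatal covariate (-0.11, adjusted p = 0.0384). Their mean was -0.032 (adjusted p = 0.407) with batch as a block, and -0.0093 (adjusted p = 0.516), -0.021 (adjusted p = 0.538) and -0.015 (adjusted p = 0.360) without control animal 6, PIO animal 9 and PIO animal 11 in turn. Of these, Nr4a3 differed by -0.27 (SE 0.088), Arc by -0.40 (SE 0.22), Btg2 by -0.36 (SE 0.19) and Bdnf by -0.048 (SE 0.079).

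Metabolic and stress lists gave no call in the planned fit. Insulin and glucose signalling genes had a median of -0.010 and a mean of 0.0056, with an adjusted p of 0.355 in the direction of lower. Their mean ranged from -0.020 (without control animal 7) to 0.033 (without PIO animal 9) with 1 animal left out. Grb10, an inhibitor of the insulin receptor, differed by 0.19 (SE 0.084), Igfbp5 by -0.14 (SE 0.066), Igf1 by -0.19 (SE 0.10) and Insr by -0.039 (SE 0.062), or -0.084 (SE 0.049) without PIO animal 10. Heat shock and unfolded protein genes had 21 of 31 higher, a mean of 0.030 and an adjusted p of 0.190. They passed as higher without PIO animals 14 to 16 and in 3 fits with tissue covariates, with means between 0.037 and 0.057 and adjusted p between 0.00145 and 0.0262. Their mean was 0.013 (adjusted p = 0.460) without control animal 7 and 0.0095 (adjusted p = 0.688) without PIO animal 13. The chaperone genes Hspa1b, Dnajb9 and Hsp90b1 differed by 0.24 (SE 0.080), 0.10 (SE 0.047) and 0.14 (SE 0.069). Antioxidant genes had a median of 0.013 and a mean of 0.057, while the test direction was lower (adjusted p = 0.983), with Gpx3 at 0.74 (SE 0.24), Gstm5 at -0.14 (SE 0.049) and Gstm1 at -0.14 (SE 0.060). Glucocorticoid target genes had 11 of 19 higher and an adjusted p of 0.729, and passed as higher with the myelin covariate (0.11, adjusted p = 0.0168). With 1 animal left out their mean ranged from -0.0088 (without PIO animal 10) to 0.076 (without PIO animal 9), and members were Plin4 at 0.48 (SE 0.32), Sult1a1 at 0.30 (SE 0.22) and Cdkn1a at 0.21 (SE 0.17). Clock genes had a median of 1.81e-04, a mean of -0.0066 and a test direction of higher (adjusted p = 0.746). Their mean ranged from -0.033 (without control animal 2) to 0.020 (without PIO animal 10) with 1 animal left out. Members were Clock at 0.10 (SE 0.038), with only 2 of its 4 probe sets moving that way, Nfil3 at 0.19 (SE 0.088) and Rorb at -0.34 (SE 0.13). Cytosolic ribosomal protein genes had 24 of 42 lower, a mean of -0.0083 and an adjusted p of 0.210. They passed as lower without PIO animal 14 (-0.016, adjusted p = 0.0470), without PIO animals 14 to 16 (-0.031, adjusted p = 0.00517) and with the choroid, striatal and thalamic covariates (-0.026, adjusted p = 0.0175), while their mean was 9.91e-04 (adjusted p = 0.445) without PIO animal 11. The smallest p among them was that of Rpsa, at -0.14 (SE 0.050), followed by Rps4x and Rpl4 at -0.057 and -0.053.

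Neuronal lists did not pass in the planned fit either. Pyramidal and granule neuron markers had 10 of 15 lower, a mean of -0.035 and an adjusted p of 0.190, and passed as lower without PIO animal 11 (-0.057, adjusted p = 0.0356), while without PIO animals 14 and 15 in turn the mean was -0.016 and -0.014. Members were Thy1 at -0.13 (SE 0.064), Nefh at -0.11 (SE 0.064) and Nefm at -0.093 (SE 0.054). Young neuron and proliferation markers had 7 of 8 higher, a mean of 0.089 and an adjusted p of 0.0750. The young neuron list passed as higher without PIO animal 13, 14 or 15 in turn, without those numbered 14 to 16 together and in 4 other fits, with adjusted p between 0.0152 and 0.0469, while in arrays 10 to 24 the mean was 0.032 (adjusted p = 0.494). Sox4 and Sox11, transcription factors of newly formed neurons, differed by 0.16 (SE 0.051) and 0.35 (SE 0.13), and Sox4 passed when adjusted over the list alone (adjusted p = 0.0498). Dentate granule layer genes had 13 of 18 lower, a mean of -0.099 and an adjusted p of 0.0940. They passed as lower with batch as a block, with the choroid covariate, in arrays 10 to 24 and without control animal 1 or PIO animal 10 or 11 in turn, with adjusted p between 0.0115 and 0.0465, but the mean was -0.050 and -0.056 without PIO animals 14 and 15 in turn, 0.022 with the myelin covariate and 0.038 without PIO animals 14 to 16. Among the members C1ql3 differed by 0.11 (SE 0.040) and Stxbp6 by -0.12 (SE 0.045), but only 1 of the 2 probe sets of Stxbp6 moved that way. CA1 markers had 6 of 9 lower and an adjusted p of 0.665, with Lypd1 at 0.40 (SE 0.17), Fibcd1 at -0.28 (SE 0.17) and Pou3f1 at -0.17 (SE 0.12). CA2 and CA3 markers had a median of -0.033, a mean of 0.024 and a test direction of higher (adjusted p = 0.909). They passed as higher without PIO animals 14 to 16 and in 3 fits with tissue covariates, with means between 0.089 and 0.11 and adjusted p between 0.00714 and 0.0314, while the mean was -0.0012 (adjusted p = 0.506) without PIO animal 10. Members were Nnat at 0.25 (SE 0.081), Pcp4 at 0.22 (SE 0.085) and Trhr at 0.30 (SE 0.12). Inhibitory neuron markers had 12 of 20 higher and an adjusted p of 0.665, with somatostatin (Sst) at 0.15 (SE 0.056), parvalbumin (Pvalb) at -0.28 (SE 0.11) and Dlx2 at 0.088 (SE 0.043).

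Markers of tissue next to the hippocampus differed widely between animals. Choroid plexus and ependyma genes rose by the preset test, with 22 of 23 higher, a median of 0.86 and a mean of 0.92 (camera adjusted p = 0.00384; adjusted p = 0.803 with an estimated correlation). The array means were -0.46 ± 1.93 in controls and 0.46 ± 1.58 with PIO (SD, n = 8 each), so the difference was smaller than the SD of either group, and the exact permutation p was 0.307. The means lay between -2.51 and -1.43 in control animals 1, 4, 5 and 7 and PIO animals 9 and 13, and between 0.24 and 1.95 in the others. Ttr, transthyretin, was at 14.24 ± 2.42 in controls and 15.39 ± 2.22 with PIO (SD, n = 8 each). Otx2, Calml4 and Cldn1 differed by 1.56 (SE 1.04), 1.63 (SE 1.13) and 0.67 (SE 0.35). The call was lost without control animal 1 (mean 0.63, adjusted p = 0.149), without control animal 4 (0.67, adjusted p = 0.0665), without PIO animal 11 (0.71, adjusted p = 0.0924) and in the largest array batch (0.46, adjusted p = 0.112). It was lost in arrays 10 to 24 as well (0.88, adjusted p = 0.428). The leading principal component held 35.0% of the variance, and 12 of the 25 genes with its largest loadings were on the choroid list.

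Striatal markers had 10 of 13 higher with PIO, a mean of 0.21 and an adjusted p of 0.0628. Syndig1l, Penk (proenkephalin) and Gpr6 differed by 0.39 (SE 0.099), 0.77 (SE 0.33) and 0.81 (SE 0.37), and Syndig1l passed when adjusted over the list alone (adjusted p = 0.0155). The striatal array means were highest in PIO animals 15 (0.74) and 14 (0.63), followed by control animal 7 (0.30). Without PIO animals 15 and 14 in turn the list mean was 0.12 and 0.13, and without 14, 15 and 16 together 0.0080, while the list passed as higher with batch as a block (0.25, adjusted p = 0.0105), in 3 other fits on all arrays and without each of 6 other animals in turn. Thalamus and habenula markers had 14 of 16 higher, a mean of 0.21 and an adjusted p of 0.0628, with an array mean of 0.98 in PIO animal 16. Without that animal the list mean was 0.079 (adjusted p = 0.706) and in the largest array batch 0.060 (adjusted p = 0.556), while the list passed as higher with batch as a block (0.20, adjusted p = 0.0316), in 5 other fits on all arrays and without each of 7 other animals in turn. Ntng1, Rgs16 and Tac2 differed by 0.25 (SE 0.098), 0.36 (SE 0.17) and 0.59 (SE 0.30). Neocortex and subiculum markers had 10 of 18 higher and an adjusted p of 0.746. Rorb, the member with the smallest p, was at -0.34 (SE 0.13), and Calb1 and Pcdh8 were at 0.15 (SE 0.059) and 0.15 (SE 0.077). Endothelial markers had a median of 0.025, a mean of -0.047 and an adjusted p of 0.360 in the direction of lower. PIO animals 9 and 10 had array means of -0.61 and -0.59 against 0.017 to 0.36 in the other PIO animals, and without either in turn the list mean was 0.036 and 0.034. The list passed as lower with the myelin covariate (-0.23, adjusted p = 3.49e-06), in the largest array batch (-0.15, adjusted p = 0.0225), with the choroid, striatal and thalamic covariates (-0.23, adjusted p = 4.33e-05) and in 4 other fits, all of them with PIO animals 9 and 10, and had a mean of 0.12 (adjusted p = 0.372) in arrays 10 to 24, which leave them out. Single members were Tek, Slco1a4 and Ctla2a at -0.44 (SE 0.17), -0.24 (SE 0.14) and 0.24 (SE 0.14). Pericyte, smooth muscle and leptomeningeal markers had 16 of 21 higher, a mean of 0.12 and an adjusted p of 0.675. The list passed as lower in the largest array batch (-0.31, adjusted p = 0.00733) and with the choroid, striatal and thalamic covariates (-0.27, adjusted p = 0.00624), and as higher in arrays 10 to 24 (0.64, adjusted p = 2.55e-04), so its direction depended on which arrays and covariates were used. With 1 animal left out its mean ranged from -0.0065 (without PIO animal 11) to 0.26 (without PIO animal 9). Members were Dcn, Abcc9 and Lum at 0.16, -0.091 and -0.21. Of the blood cell markers 1 was measured, so that list was not tested.

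**Figure D4:**
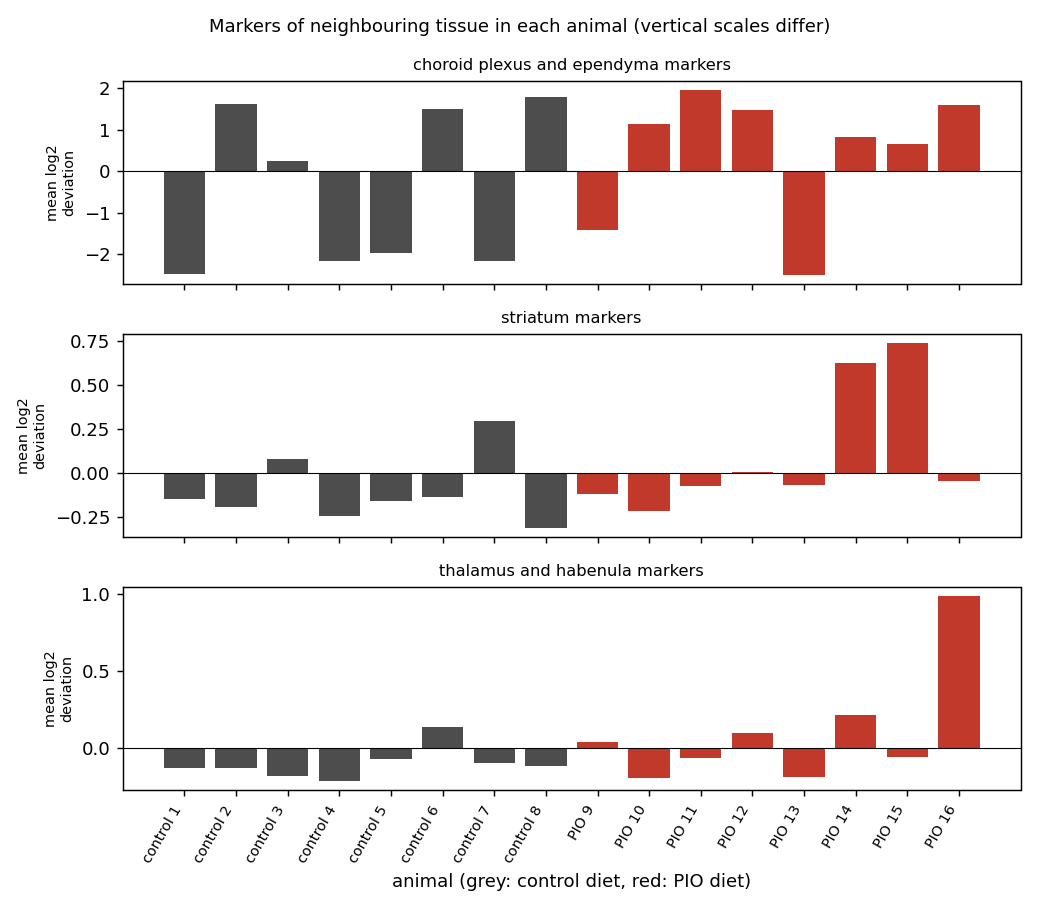
Mean log2 deviation of the choroid plexus and ependyma, striatum, and thalamus and habenula marker lists in each of the 16 animals (vertical axes, scales differ), control animals in grey and PIO animals in red. Choroid markers lie below -1.4 in 6 animals of both groups, striatal markers are highest in PIO animals 14 and 15, and thalamic markers are highest in PIO animal 16 at 0.98.

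The striatal markers moved against the myelin list. Within groups, the 2 array means correlated with r = -0.702 (permutation p = 0.00345, adjusted p = 0.0130 over 5 relations) and rho = -0.806 (permutation p = 1.80e-04, adjusted p = 9.00e-04). Without the 2 animals farthest from the striatal median r was -0.430, and within the largest array batch it was -0.582 over 11 arrays. Striatal markers also correlated with pyramidal and granule neuron markers at r = -0.661 (permutation p = 0.00519, adjusted p = 0.0130) and rho = -0.662 (permutation p = 0.00644, adjusted p = 0.0161). For this pair r was weaker without those 2 animals, at -0.279, but within the largest batch it was -0.736. With microglial markers the striatal markers had r = -0.261 (permutation p = 0.329, adjusted p = 0.336) and rho = -0.309 (permutation p = 0.244, adjusted p = 0.244). Thalamic and microglial markers had r = -0.363 (permutation p = 0.174, adjusted p = 0.289) and rho = -0.456 (permutation p = 0.0807, adjusted p = 0.134). Microglial and myelin markers had r = 0.258 (permutation p = 0.336, adjusted p = 0.336) and rho = 0.329 (permutation p = 0.214, adjusted p = 0.244). For these 3 pairs r was -0.148, -0.432 and 0.326 without the 2 farthest animals and -0.0063, -0.368 and 0.0911 within the largest batch. Without PIO animals 14, 15 and 16, a choice made after the marker values were seen, the myelin and microglial lists kept their preset-correlation calls at means of -0.11 (adjusted p = 5.77e-04) and -0.14 (adjusted p = 0.00161), and the cholesterol efflux list at -0.089 (adjusted p = 0.00831). With the choroid, striatal and thalamic means together as covariates the myelin and microglial lists kept their preset-correlation calls at -0.11 and -0.14, while the differences of their array means in that fit, -0.112 (SE 0.0841) and -0.139 (SE 0.127), lay within 2 SE of 0. With all animals and an estimated correlation both lists had lost their calls (adjusted p = 0.527).

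RNA quality measures differed between the groups by less than the spread between animals. The 3' minus 5' signal of the actin control probe sets was 0.826 ± 0.053 log2 units in controls and 0.833 ± 0.055 with PIO (SD, n = 8 each; exact permutation p = 0.805), and that of Gapdh had an exact permutation p of 0.944. Two-sided tests were used throughout. By limma's fry 0 lists passed the adjusted threshold of 0.05 and 1 passed before adjustment, as with an estimated correlation in camera. In both tests the 1 list was that of young neurons and proliferating cells. By exact permutation of the array means the counts were also 0 and 1, but the list was another. It was that of the PPAR and RXR family receptors and coregulators. None of the 8 lists called with the preset correlation passed before adjustment in any of these tests.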

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

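The tests of array batch, of array number and of diet as the source of the choroid split, and the choroid, striatal and thalamic covariates, were chosen only after the result was seen, and the other tests of this part before it. A value is given here where 1 animal of a group of 8 stood apart from the rest by more than Dixon's 95% limit for the gap over the range. This held for 19 of 362 groups of values, where chance alone gives about 18, so no pattern is read from the number.

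Among genes, control animal 5 stood apart for Myh7b at 7.54 against a median of 6.92 in its group and for Lypd1 at 10.18 against 9.43. Control animal 4 did so for Cd36 at 3.88 against 4.49, for Ctla2a at 6.35 against 6.89 and for Fkbp1b at 10.76 against 10.46. PIO animal 10 did so for Grin3a at 8.69 against 9.17, for Hspa1b at 11.25 against 10.67 and for Insr at 9.01 against 8.63. PIO animal 13 did so for Apba2 at 11.23 against 11.05 and for Calml4, a choroid plexus marker, at 3.60 against 9.05. Single values were those of PIO animal 11 for Ppara at 5.22 against 4.74, control animal 3 for Igfbp5 at 12.02 against 11.63, control animal 8 for Cxcl10 at 5.40 against 4.27, PIO animal 12 for Osmr at 7.91 against 7.26, PIO animal 9 for Dlx2 at 7.71 against 7.48 and control animal 1 for Stxbp6 at 12.16 against 12.39. Among list means, the heat shock list was at 0.16 in PIO animal 13 against -0.012, and the thalamus list was at 0.98 in PIO animal 16 against -0.061 and at 0.13 in control animal 6 against -0.13.

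Choroid plexus markers split the arrays in both groups. Within groups the median correlation of a choroid marker with the mean of the other markers was 0.974, as choroid plexus tissue taken along with some hippocampi would give, and the ependymal genes Foxj1, Tmem212 and Ccdc153 followed less closely at 0.747, 0.476 and 0.426. The control group alone spanned 4.29 log2 units and the PIO group 4.46, which argues against diet as the source of the split. Choroid tissue carried over in dissection is a candidate explanation for the spread, and whether diet adds a smaller shift stays open.

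For the lower microglial and myelin lists, with the choroid, striatal and thalamic list means as covariates, the difference of the array means was -0.139 (SE 0.127) for microglia, against -0.224 without them, and -0.112 (SE 0.0841) for myelin, against -0.184. In the largest array batch it was -0.138 (SE 0.138) for microglia and -0.0663 (SE 0.0815) for myelin, while with batch as a block it was -0.236 (SE 0.119) and -0.192 (SE 0.0888). In arrays numbered 10 to 24 it was -0.0769 (SE 0.161) and -0.262 (SE 0.121), and with array number as a block -0.191 (SE 0.113) and -0.165 (SE 0.0975). Over all arrays the exact permutation p was 0.0608 for microglia and 0.0659 for myelin, so neither difference was clear of the spread between animals. At least 1 value for each explanation lay within 2 SE of 0, which fewer arrays or added terms would readily give. These values therefore cannot tell neighbouring tissue, array batch or array number apart from diet. For myelin the value with batch as a block and that in arrays 10 to 24 lay beyond 2 SE, and those arrays hold PIO animals 14 and 15. An effect of diet on these lists stays open.

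Other splits of the arrays bear on the counts. For genes past the adjusted threshold the real count was 0 and the highest of the other splits 41, for genes before adjustment 859 and 2329, and for lists past camera's preset test 8 and 22. The median of the other splits was 515 genes before adjustment and 9 lists. Of 100 splits, the real one included, 20 had as many genes before adjustment and 63 as many lists, so chance cannot be excluded for these 2 counts. For genes past the adjusted threshold all 100 did, as they must with a real count of 0, so that comparison tests nothing. The splits with 2329 and 2097 genes before adjustment may reflect a structure among the samples other than diet, and what those splits share was not tested.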

How the results depend on the processing

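The striatal covariate, the choroid, striatal and thalamic covariates together, the fit without PIO animals 14, 15 and 16, the 2 array number fits and the exact permutation of array means were chosen only after the result was seen. In every alternative run 0 genes passed the adjusted threshold, and the smallest adjusted p was 0.0862, with the choroid, striatal and thalamic covariates. Genes at an unadjusted p under 0.05 numbered 859 in the planned fit, 1649 with every probe set on its own, where more tests were made, 436 with the myelin covariate, 534 without PIO animals 14 to 16 and 290 in the largest array batch, where fewer arrays were used. Lists past the threshold numbered 8 and between 5 and 12 in the camera fits with the preset correlation, the 5 being in arrays 10 to 24, but 0 with an estimated correlation, 0 by fry and 0 by exact permutation of array means, where the correlation between members enters the test. The myelin list kept its call in every camera fit with the preset correlation in which it was tested, and the cholesterol efflux and microglial lists in all but that of arrays 10 to 24. Of the 29 lists not called, 22 changed sign and 16 passed in some alternative with no single animal left out, and 11 passed with 1 animal left out. Of 2538 values of the named genes, the 8 called lists and the 2 PPAR lists, recomputed without leaving out a single animal, 2482 kept their sign and side of the threshold. With 1 animal left out 2419 of 2432 did so, and the other uncalled lists are not in these counts. Most of these values are of genes, and no gene passed in any fit, so a gene could change only in sign. The high agreement was therefore largely given in advance. The calls that were lost with the sign kept, 21 and 7 in the 2 counts, were all of lists. In arrays 10 to 24 the cholesterol efflux list (0.026) and the fatty acid synthesis list (0.0023) changed sign and lost their calls as well. No other result that changed sign had passed the threshold in the planned fit. In the same arrays Scd1 was at 0.026, Osmr at 0.076, Lum at 0.13 and Ppargc1a at -0.0080. Without probe sets of shared sequence, Hmgcs1 was at -0.038 and Ppargc1a at -0.0048. App was at 0.0046 after quantile normalization and Ppargc1a at -0.017 with array weights. In the largest batch Abcc9 was at 0.030, Ppargc1a at -0.052, Pdk4 at -0.13, App at 0.041, Bace1 at -0.078, Mbp at 0.0098 and Bdnf at 0.053. With the choroid covariate App was at 0.0010, Ttr at -0.012 and the PPAR target list at -0.023, where the list passed at an adjusted p of 0.0211, and with the filter at the 60th percentile that list was at -0.024. With the myelin covariate Sox10 was at 0.019, App at 0.0019, Bace1 at -0.069 and Mbp at 0.0071, and with the striatal covariate Bace1 was at -0.045. With the choroid, striatal and thalamic covariates Pdk4 was at -0.017, App at 0.0081, Bace1 at -0.067, Ttr at -0.22 and Mbp at 0.0041. Without PIO animals 14 to 16 Pdk4 was at -0.033, App at 0.0070, Bace1 at -0.067 and Mbp at 0.0097. With 1 animal left out App ranged from -0.020 to 0.0079, Bace1 from -0.010 to 0.059, Ppard from -0.0024 to 0.066 and Ppargc1a from -0.020 to 0.074. Leaving out shared-sequence probe sets changed the probe set that stood for the gene, and the cause of the other changes was not tested. The larger pseudocount was not run because the values were already on a log2 scale. Low signal limits Pparg, Cxcl10, Cd36, Ppara and Angptl4, whose mean values lay between 3.43 and 4.77.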

Other observations

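The list of LXR target genes and the test of array number were chosen only after the values were seen, and the test of glial makeup was set before its result was seen. Several of the lower genes in the lipid lists are known targets of the liver X receptors (LXR), which sense oxysterols and drive cholesterol export and fatty acid synthesis. Of 14 such genes 13 were measured, 12 were lower with PIO and 8 of them had an unadjusted p under 0.05, namely Mylip, Abcg1, Scd2, Scd1, Abca1, Apoe, Fasn and Srebf1. Fasn, the fatty acid synthase gene, differed by -0.11 (SE 0.048), and Srebf1, which encodes the lipogenic factor SREBP1, by -0.33 (SE 0.15). Pltp went the other way at 0.054 (SE 0.21). The array means of the set were 0.089 ± 0.20 in controls and -0.089 ± 0.10 with PIO (SD, n = 8 each). Control animals 1 to 4 lay between 0.21 and 0.29, while control animals 5 to 8, between -0.18 and 0.099, overlapped the PIO animals, between -0.22 and 0.053. The difference was -0.18 (SE 0.079; exact permutation p = 0.0452) and -0.20 (SE 0.098) in the largest array batch. The set was chosen after several of its members were seen to be lower, and 11 of the 13 genes stand on lists already described. The counts and this p are therefore not independent evidence.

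In arrays numbered 10 to 24, with 4 control and 6 PIO animals, the difference was -0.0152 (SE 0.0756), and with the 2 ranges of array number as a block it was -0.127 (SE 0.0661). PIO animals 9 and 10, in the lower range of array numbers with control animals 1 to 4, were at -0.16 and 0.010. Array number and diet therefore cannot be told apart here, because the lower range holds only 2 PIO arrays and these went with the PIO group. Whether diet had any part in the difference stays open. An alternative for the lower mean with PIO is that fewer glial cells were sampled, since many of these genes are expressed mostly in glia. With the microglial, astrocyte and myelin list means as covariates the difference was -0.0923 (SE 0.0736), over 50% of the unadjusted value but within 2 SE of 0. This explanation cannot be told apart from the others with 16 arrays. PPAR target genes were not called as a group, and levels of oxysterols or LXR protein were not analysed here.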
